A study of Rattus norvegicus with 4 samples.

How the data were processed

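Ribosome-protected fragments were measured in 4 libraries of cultured rat myocardial cells, 2 given a control siRNA (siNT) and 2 given an siRNA against the translation initiation factor subunit eIF3m (si3m). Per the labels' protocols, translation was halted with cycloheximide, ribosomes were separated by ultracentrifugation, the monosome and polysome fractions were collected, and libraries were built with a kit for small RNA. Nothing in the labels says whether the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. RNA-seq libraries of the same cells were not analysed here, so every value is footprint abundance and not translational efficiency.

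The deposited files hold whole-number counts per gene, with no normalization and 31038 rows in each of the 4 libraries. The submitters' processing notes name Trimmomatic 0.40, HISAT2 2.2.1, featureCounts, limma, DESeq2 and the rat genome build rn6. The role of each tool, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be assigned with certainty. Between 94.9% and 97.3% of the counts above 0 in a library were even numbers, as if most fragments had been counted as 2 reads, so sampling noise was judged on fragments (deposited counts divided by 2). A spreadsheet had turned 27 gene symbols into dates, and 2 of these dates occurred more than once. Those rows, with 0.235% ± 0.00716 of the counts in siNT and 0.250% ± 0.000906 in si3m (SD, n = 2 each), stayed in the fit but are not named.

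Gene symbols were matched to a table of RefSeq genes of the assembly GRCr8, 20669 by current symbol and 2100 by synonym, together 22769 of 31038. The unmatched rows held 15.2% ± 0.0860 of the siNT counts and 17.7% ± 0.873 of the si3m counts (SD, n = 2 each). That assembly is not the build of the files, so the table served for names, gene type and neighbouring genes, and no coordinates are printed.

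Total counts were 3924434 and 3835750 in siNT replicates 1 and 2, and 8687598 and 6726969 in si3m replicates 1 and 2. A count of 0 allowed up to 3 fragments (6 deposited counts), equal to 1.53, 1.56, 0.691 and 0.892 CPM (counts scaled to a common library size) in that order. Such limits, and the interval given for Has2, cover counting error only, and reads were counted without molecular identifiers. Between replicates, over rows with at least 20 fragments per pair, the median chi-square was 1.40 times that of pure counting noise in siNT and 1.44 times in si3m. Both pairs were kept as 2 samples, although this excess cannot tell separate cultures from repeat preparations of the same culture.

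Genes were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default minimum count of 10, TMM scaling, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Replicate number was not used as a block. Mean CPM values are TMM-scaled unless a share of the library total is stated. Gene lists were compared with camera in limma 3.58.1 on the same counts, two-sided, with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists that had at least 5 tested genes. In all 42 lists of textbook membership were drawn up, and 1053 of their 1062 entries matched a row, 36 of them through a synonym. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera has few residual degrees of freedom here, with 2 libraries per group, and so little power.

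The design, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule named Eif3m and the other eIF3 subunits. It further took the 12 largest rises and 12 largest falls among genes past the threshold with at least 10 mean CPM, a symbol other than a bare predicted locus, and both si3m values on the same side of both siNT values. From each list that passed, and from 5 lists chosen by topic whether or not they passed, it took up to 4 members with the smallest p. It also took the highest-count gene of each library. The result of 1 gene named by the rule is not reported here. Genes, markers and classes outside this rule are said to have been chosen after their values were seen.

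Counts were simulated for this comparison from the same 12672 genes, means and library sizes. Every gene was given the common dispersion (spread between replicates) of 0.0109, and counts were not doubled, unlike the deposited ones. On these counts the test recovered 22.6% of 62 genes changed 1.5-fold, 68.6% of 70 changed 2-fold and 92.6% of 68 changed 4-fold. It called 7 of 12202 unchanged genes. Alternative settings were DESeq2 size factors, upper quartile and total count scaling, no low-count filter, a stricter filter of 50 counts in 2 samples, the replicate block, leaving out each library, leaving out mitochondrial and non-coding rows, robust quasi-likelihood, the Wald test of DESeq2 1.42.0, limma-voom, and a log2 fold change over 1. Settings for values already normalized did not apply to counts. After the even counts had been seen, halved counts and halved counts thinned to 1917654 fragments per library were added. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.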

Results

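Footprints of ribosomes were counted per gene in 4 libraries of rat myocardial cells. Their label NRVM usually stands for neonatal rat ventricular myocytes, whereas the labels' protocols name embryonic rat heart. This conflict was not resolved. The siNT group (control siRNA) and the si3m group (siRNA against eIF3m) had 2 libraries each. eIF3m is a subunit of eIF3, the complex that joins the small ribosomal subunit and helps bring it to messenger RNA. Depth differed with group, with total counts of 3924434 and 3835750 in siNT and 8687598 and 6726969 in si3m. The highest count in every library fell on the predicted locus LOC102557338, at 58320 ± 379 CPM in siNT and 57051 ± 160 CPM in si3m (SD, n = 2 each). Its log2 fold change of -0.03 (SE 0.0065, edgeR adjusted p = 0.00177) lost its call under several alternatives, including without siNT replicate 2 (adjusted p = 0.207). Of 18 cardiomyocyte genes, chosen after their values were seen, 10 to 15 had at most 6 counts in a library. The 18 summed to between 109 and 132 CPM of the library total, whereas the collagen gene Col1a1 alone reached 3845 to 6663.

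Eif3m, the gene targeted by the siRNA, had deposited counts of 2136 and 1774 in the siNT libraries and 1168 and 1232 in the more deeply sequenced si3m libraries. Its footprint abundance fell 3.01-fold, from 491 ± 57.3 CPM to 164 ± 37.5 CPM (SD, n = 2 each; log2 fold change -1.59, SE 0.11). The change passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 3.41e-08), and both si3m libraries lay below both siNT libraries. With robust quasi-likelihood the fold change was the same and the adjusted p was 0.0522, the highest over the 16 alternatives.

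Other subunits of eIF3 moved in both directions. Eif3j, a loosely bound subunit, fell 1.68-fold (log2 -0.75, SE 0.083, adjusted p = 5.99e-06), and Eif3a, the largest subunit, fell 1.22-fold (log2 -0.28, SE 0.051, adjusted p = 5.71e-04). Eif3d rose by 0.68 on the log2 scale (SE 0.094, adjusted p = 5.92e-05), Eif3h by 0.58 (SE 0.081) and Eif3e by 0.53 (SE 0.085, 1.44-fold). Eif3i (log2 0.54), Eif3b (log2 0.19) and Eif3c (log2 0.12) passed with adjusted p between 0.0388 and 0.0481. Those 3 calls were lost under several alternatives. Eif3b and Eif3i did not pass without siNT replicate 1 (adjusted p = 0.230 and 0.123), and none of the 3 passed without si3m replicate 1 (0.0543 for Eif3b, 0.173 for Eif3c and 0.238 for Eif3i) or without si3m replicate 2 (0.224, 0.0860 and 0.0976). Eif3f, Eif3g, Eif3k and Eif3l had log2 values of -0.16, -0.12, -0.25 and 0.07 and did not pass, Eif3l turning to -0.01 with total count scaling and moving to 0.02 without si3m replicate 2 and 0.14 without si3m replicate 1. Eif3k passed with total count scaling (log2 -0.33, adjusted p = 0.04997) and with thinned counts (log2 -0.41, adjusted p = 0.0259), and Eif3f moved to -0.06 without siNT replicate 1. Of the 13 subunits tested, 6 were higher and 3 lower, and the counts were the same adjusted over the list alone. As a list they did not pass camera (adjusted p = 0.902).

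**Figure D1:**
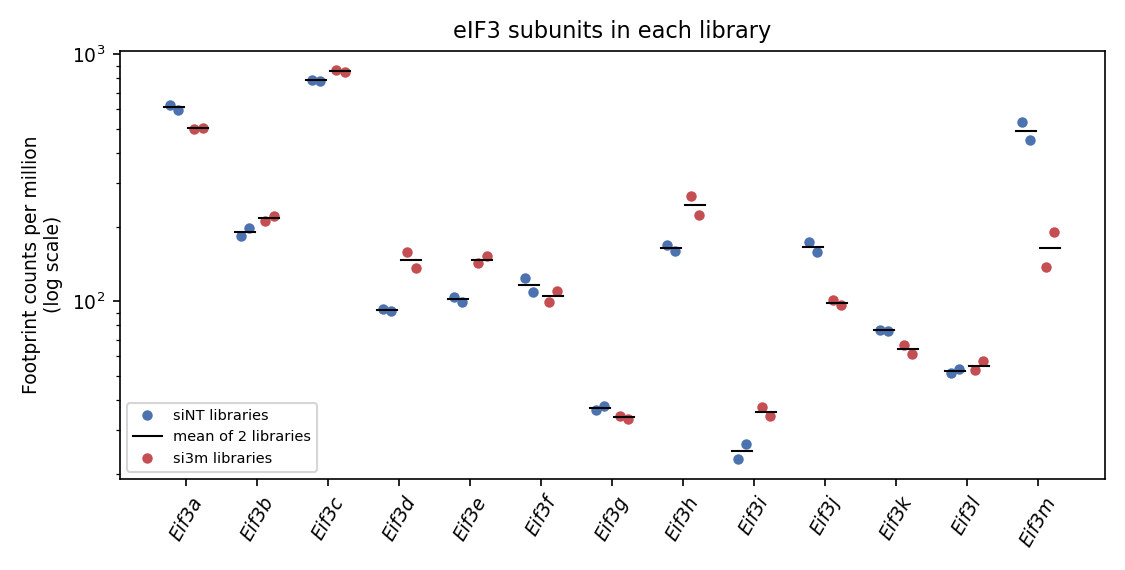
Footprint abundance in CPM (log axis) of 13 eIF3 subunits, with a point for each of the 2 siNT and 2 si3m libraries and a line at each group mean. Eif3m has the largest gap between groups, 491 against 164 CPM, while Eif3d, Eif3e and Eif3h are higher in si3m and Eif3a and Eif3j are lower.

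The question put to the whole set of genes was which footprints change when eIF3m is reduced, the series title placing this factor in nitrative damage after ischemia and reperfusion of the heart. Of 12672 genes tested, 3528 changed, 1771 higher and 1757 lower in si3m. Total count scaling moved this split to 1428 higher and 2217 lower. TMM scaling centres the fold changes (median log2 0.016 over all tested genes), so every rise or fall is relative to the other footprints. A change in the total amount of translation would not show. Values of the groups did not overlap for 63.9% of tested genes, where chance gives 33.3%.

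Has2, the enzyme that makes hyaluronan, rose from near absence, with deposited counts of 2 and 4 in siNT and 7156 and 5236 in si3m. In fragments the ratio was 1098-fold (95% interval 376 to 5327, counting error only), and the edgeR adjusted p was 1.24e-17. Mettl26, a putative methyltransferase gene, rose 11.4-fold, from 4254 ± 20.7 CPM to 48675 ± 265 CPM (SD, n = 2 each; log2 3.52, SE 0.010, adjusted p = 1.29e-26). Casp16 rose 6.19-fold (log2 2.63, SE 0.048), from 237 ± 7.70 CPM to 1466 ± 6.34 CPM (SD, n = 2 each). Ndufa1, a subunit of respiratory complex I, rose 6.88-fold (log2 2.78, SE 0.15), and Bax, which permeabilizes the outer mitochondrial membrane in apoptosis, rose 4.52-fold (log2 2.18, SE 0.18). Cxcl10, an interferon-induced chemokine, rose 5.54-fold (log2 2.47, SE 0.32). Spc25, a kinetochore protein, rose 4.31-fold (log2 2.11, SE 0.29), and Cdca3, a mitotic regulator, 4.14-fold (log2 2.05, SE 0.29). The histone genes Hist2h3c2 and Hist1h2ail1 rose 8.97-fold (log2 3.17, SE 0.16) and 4.23-fold (log2 2.08, SE 0.25), with reads that near-identical histone copies could share. Arl5c, of the ARF-like GTPase family, rose 5.43-fold (log2 2.44, SE 0.071), and Prtfdc1, of the phosphoribosyltransferase family, 5.27-fold (log2 2.40, SE 0.11). In the GRCr8 annotation Has2 overlaps the long non-coding RNA LOC108351495, and Mettl26 and Casp16 each span at least 1 tRNA gene. Of 82 named genes matched to that annotation, 22 overlap a gene with its own row, Mettl26, Cdca3, Cxcl10 and Spc25 among them, and counts of such genes are uncertain.

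**Figure D2:**
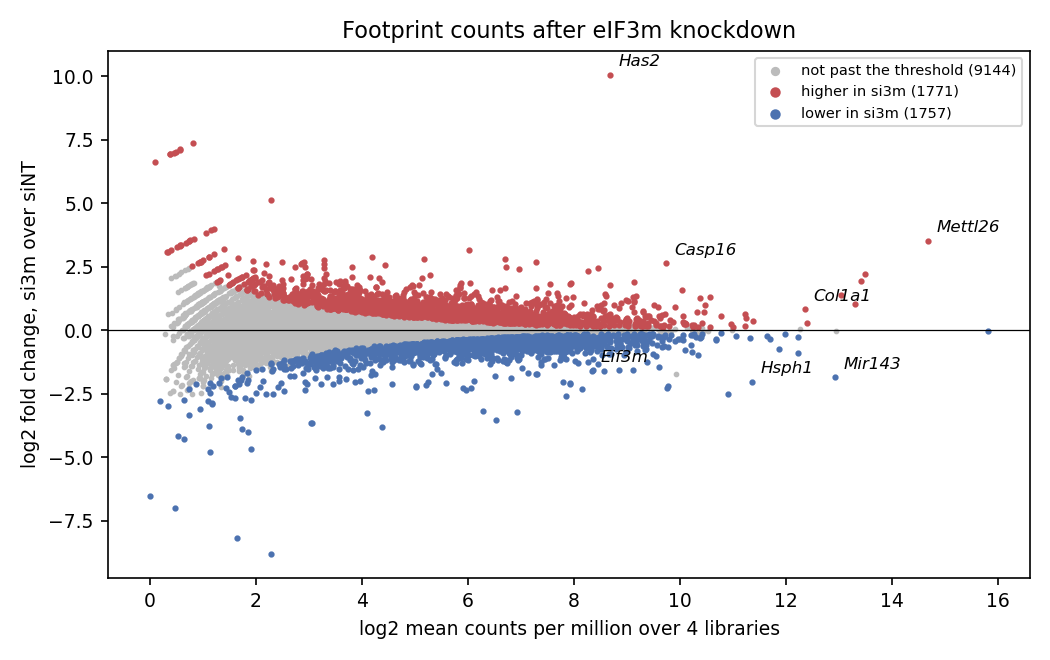
Log2 fold change of si3m over siNT against log2 mean CPM for 12672 genes, a point each, coloured by whether the edgeR adjusted p was under 0.05 and by direction. Has2 stands highest at 10.06 and Mettl26 at 3.52, while Eif3m lies at -1.59, Hsph1 at -2.03 and the microRNA gene Mir143 (labelled after its value was seen) at -1.85.

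All 12 of the largest falls by the rule were microRNA genes, which code for short RNAs that repress messenger RNAs and are not translated. Mir101-2 fell 11.6-fold, from 171 ± 19.9 CPM to 14.7 ± 0.210 CPM (SD, n = 2 each; log2 -3.53, SE 0.13, edgeR adjusted p = 1.18e-11). Mir34a, a target of p53, fell 9.54-fold (log2 -3.25, SE 0.30), Mir101a 9.45-fold (log2 -3.24, SE 0.13) and Mir542 9.23-fold (log2 -3.21, SE 0.13). Mir30a fell 5.97-fold (log2 -2.58, SE 0.100) and Mir708 5.32-fold (log2 -2.41, SE 0.25). Mir103a1, Mir20a, Mir152, Mir16, Mir103a2 and Mir7a-2 fell between 4.83-fold and 5.20-fold. Mir103a1 and Mir103a2, and Mir7a-2 and its copy, share mature sequences, those of Mir101a and Mir101-2 are alike, and the separate counts of all are uncertain. Mir34a overlaps the locus LOC103692514, and Mir101-2, Mir103a1, Mir103a2, Mir152, Mir16 and Mir708 overlap protein-coding genes. Rows of microRNA genes took 3.19% ± 0.0533 of all counts in siNT and 1.11% ± 0.122 in si3m (SD, n = 2 each).

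Proteins of the cytosolic ribosome rose as a list. Of 79 tested members, 43 rose and 6 fell, or 47 and 8 adjusted over the list alone, with a median log2 fold change of 0.40. Rpl41 rose 2.70-fold (log2 1.43, SE 0.057), Rps29 1.84-fold (log2 0.88, SE 0.070), Rps3 1.76-fold (log2 0.82, SE 0.058) and Rplp0 1.62-fold (log2 0.70, SE 0.051). The list passed camera (adjusted p = 2.28e-08), and the call was lost at adjusted p = 0.26 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes with which reads can be shared.

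Factors of translation elongation and release also rose, with 8 of 10 tested members higher and the other 2 not past the threshold (9 higher adjusted over the list alone; median log2 0.30). Eef1d, an exchange factor for elongation factor 1, rose 2.08-fold (log2 1.06, SE 0.098), and Eef2, which translocates the ribosome, 1.51-fold (log2 0.60, SE 0.044). Eif5a and Eef1b2 rose 1.35-fold (log2 0.44, SE 0.073) and 1.22-fold (log2 0.28, SE 0.057). The list's camera adjusted p was 0.00119, and adjusted p = 0.38 with an estimated correlation. Initiation factors other than eIF3 did not pass as a list (adjusted p = 0.876), with 7 of 31 higher and 7 lower, or 8 and 7 adjusted over the list alone.

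Genes of the cell cycle and DNA replication were higher in si3m. Of 36 tested members, 27 rose and 9 did not pass, with 28 higher adjusted over the list alone and a median log2 of 0.69. With total count scaling 24 were higher and 1 lower. Ccnb1, the cyclin that drives entry into mitosis, rose 2.37-fold (log2 1.25, SE 0.13), and Cenpf, a centromere protein, 2.06-fold (log2 1.04, SE 0.081). Mki67, a marker of proliferating cells, rose 1.63-fold (log2 0.70, SE 0.065), and Top2a, the topoisomerase of dividing cells, 1.44-fold (log2 0.53, SE 0.062). The list passed camera (adjusted p = 4.58e-10), a call lost at adjusted p = 0.26 with an estimated correlation.

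Fibroblast markers rose too, 11 of 12 tested members, the same number adjusted over the list alone, with a median log2 of 0.77. Only these 12 of the 18 members had enough counts to be tested. Among members chosen after their values were seen, Tcf21 had 0 counts in each library and Pdgfra at most 18. Col3a1 rose by 1.32 on the log2 scale (SE 0.056), from 331 ± 22.2 CPM to 827 ± 21.5 CPM (SD, n = 2 each), Postn, a secreted matrix protein of activated fibroblasts, 1.88-fold (log2 0.91, SE 0.048), Col1a1 1.78-fold (log2 0.83, SE 0.023) and Col1a2 1.54-fold (log2 0.63, SE 0.030). These 4 genes also belong to the list of extracellular matrix genes, in which 16 of 29 tested members rose and 7 fell (18 and 7 adjusted over the list alone; median log2 0.42). Dcn, in both lists, had 0 counts in both siNT libraries and 44 in si3m, at least 3.69-fold higher against a floor of 6 counts over the group, and neither median changed with Dcn at that bound. Camera gave adjusted p = 4.58e-10 for the markers and 3.36e-04 for the matrix list. Both calls were lost, at adjusted p = 0.26 with an estimated correlation for the markers and adjusted p = 0.33 with an estimated correlation for the matrix list.

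NF-kB targets and inflammatory cytokines were higher, 7 of 17 tested members rising and 10 not passing, the same adjusted over the list alone (median log2 0.46). Total count scaling added 1 member that was lower. Tnfaip3, a feedback inhibitor of NF-kB, rose 3.35-fold (log2 1.74, SE 0.19), and Icam1, an adhesion molecule for leukocytes, 1.75-fold (log2 0.80, SE 0.12). Csf1, a growth factor for macrophages, rose 1.48-fold (log2 0.57, SE 0.069), and Cxcl10 was the fourth named member. The list passed camera at an adjusted p of 0.00751, lost at adjusted p = 0.39 with an estimated correlation.

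Cytosolic heat shock proteins were lower in si3m, with 8 of 16 tested members falling and 1, the small heat shock protein Cryab (named after its value was seen), rising; adjusted over the list alone 8 were lower and 2 higher. Hsph1, a co-chaperone of Hsp70, fell 4.08-fold, from 4243 ± 36.2 CPM to 1040 ± 4.28 CPM (SD, n = 2 each; log2 -2.03, SE 0.029, edgeR adjusted p = 6.30e-17). Hspa8, the constitutive Hsp70, fell 2.37-fold (log2 -1.24, SE 0.072), and the chaperones Hsp90ab1 and Hsp90aa1 fell 1.41-fold (log2 -0.50, SE 0.056) and 1.39-fold (log2 -0.48, SE 0.058). Camera gave adjusted p = 1.37e-04, lost at adjusted p = 0.33 with an estimated correlation. The median log2 of -0.26 became -0.08 without siNT replicate 1, where the list still passed and 2 members were higher, as they were without siNT replicate 2.

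Lysosomal genes were lower as a list, 8 of 22 tested members falling and 2 rising, the same adjusted over the list alone (median log2 -0.14). Ctsd, a lysosomal protease, fell 1.99-fold, from 1737 ± 18.6 CPM to 871 ± 20.4 CPM (SD, n = 2 each), Npc1, which exports cholesterol from the lysosome, 1.67-fold (log2 -0.74, SE 0.084), Lamp2 1.32-fold (log2 -0.40, SE 0.036) and Ctsl 1.18-fold (log2 -0.24, SE 0.026). The camera adjusted p was 0.0338, and adjusted p = 0.39 with an estimated correlation. The call was also lost without si3m replicate 1 (0.0651), with the stricter filter (0.0666) and with thinned counts (0.0620), and the median moved to -0.05 without siNT replicate 2.

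Nuclear-encoded subunits of respiratory complex I were higher, 12 of 37 tested members rising and 3 falling, or 14 and 4 adjusted over the list alone (median log2 0.22). Ndufs4, which also spans a tRNA gene in the GRCr8 annotation, rose by 1.14 on the log2 scale (SE 0.066) beside Ndufa1, while Ndufb9 fell 1.70-fold (log2 -0.77, SE 0.082) and Ndufb6 fell by 0.59 on the log2 scale (SE 0.050). The list just passed camera (adjusted p = 0.0443), and gave adjusted p = 0.39 with an estimated correlation. Its call was lost without siNT replicate 2 (0.0935, 6 members lower), without si3m replicate 1 (0.0518), without si3m replicate 2 (0.0606, 7 members higher and a median of 0.13), with the stricter filter (0.0666) and with total count scaling (0.0628, 5 members lower), and its median moved to 0.34 without siNT replicate 1.

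Sources of nitric oxide and superoxide, the list closest to nitrative damage, had enough counts to be tested for only 14 of 25 members. They did not pass as a list (camera adjusted p = 0.377), with 3 of 14 tested members higher and 2 lower, or 4 and 2 adjusted over the list alone. Nothing is known here of the untested members. These counts depended on the libraries, with 5 of 16 higher and 2 lower without siNT replicate 1, 1 higher and 1 lower without si3m replicate 1, and 2 higher and 1 lower without siNT replicate 2 or si3m replicate 2. Only 1 was lower also with upper quartile scaling, with no low-count filter and with thinned counts. Cav1, the caveolar protein that binds nitric oxide synthase, rose 1.94-fold (log2 0.95, SE 0.057, edgeR adjusted p = 5.37e-09), and Hsp90aa1, a chaperone of nitric oxide synthase, fell as given above. Spr, an enzyme of tetrahydrobiopterin synthesis, rose 3.28-fold (log2 1.71, SE 0.44), and Cyba, a subunit of NADPH oxidase, 1.79-fold (log2 0.84, SE 0.27, adjusted p = 0.0295). Spr did not pass without si3m replicate 1 (adjusted p = 0.0520). Cyba did not pass without siNT replicate 2 (0.0893), without si3m replicate 1 (0.0819), without si3m replicate 2 (0.139), in DESeq2 (0.106) or with thinned counts (0.0920).

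Antioxidant genes and NRF2 targets went both ways, with 5 of 33 tested members higher and 7 lower, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.876). Thioredoxin (Txn1) rose 2.41-fold (log2 1.27, SE 0.062) and peroxiredoxin 1 (Prdx1) 1.99-fold (log2 0.99, SE 0.055). The ferritin heavy chain gene Fth1 fell 1.54-fold (log2 -0.62, SE 0.047).

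Targets of ATF4, the transcription factor of the integrated stress response, counted 10 of 25 tested members higher and 1 lower, the same adjusted over the list alone, and did not pass camera (adjusted p = 0.0725). They passed without siNT replicate 1 (0.0404), without si3m replicate 1 (0.0308), with no low-count filter (0.00847) and in fry (0.0364). Without si3m replicate 2 only 6 members were higher, and 2 were lower without siNT replicate 2, with total count scaling, with the stricter filter and with thinned counts. Slc7a5, an amino acid transporter, rose 1.56-fold (log2 0.64, SE 0.059), Psat1, of serine synthesis, 1.37-fold (log2 0.46, SE 0.054) and Vldlr, a lipoprotein receptor, 1.21-fold (log2 0.28, SE 0.037). Slc7a1, a cationic amino acid transporter, fell 1.46-fold (log2 -0.55, SE 0.057).

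Only 12 of 31 sarcomere genes had enough counts to be tested, and 4 were higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.90). Tnnt2, cardiac troponin T, rose 2.38-fold from 6.54 ± 0.0947 CPM to 15.7 ± 1.49 CPM (SD, n = 2 each; log2 1.25, SE 0.29). Flnc, a Z-disc crosslinker, rose 1.22-fold (log2 0.28, SE 0.058), while Myom1, an M-band protein, fell 2.26-fold (log2 -1.18, SE 0.26) and Tpm1, a tropomyosin, 1.25-fold (log2 -0.32, SE 0.056).

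In all, 9 of 38 lists passed, 7 higher and 2 lower, and none of the 9 calls held with an estimated correlation. The smallest adjusted p of camera in that setting was 0.26 over all lists. It has little power with 2 libraries per group, so these losses do not decide for or against the 9 lists. The other 29 had camera adjusted p between 0.0536 and 0.987. Mitochondrial ribosomal proteins had 13 of 74 tested members higher and 4 lower, the same adjusted over the list alone (adjusted p = 0.0536). Splicing factors had 5 of 30 higher and 12 lower, or 5 and 14 adjusted over the list alone (adjusted p = 0.0574). Genes of cholesterol synthesis had 7 of 23 higher and 1 lower, or 9 and 2 adjusted over the list alone (adjusted p = 0.0574). Calcium handling genes had 6 of 17 higher and 3 lower, or 7 and 3 adjusted over the list alone (adjusted p = 0.618). Apoptosis genes and p53 targets had 6 of 24 higher and 4 lower, the same adjusted over the list alone (adjusted p = 0.339). Mitochondrially encoded proteins had 4 of 13 higher and 3 lower, or 5 and 3 adjusted over the list alone (adjusted p = 0.987). Among markers of other cells, smooth muscle and pericyte genes had 3 of 11 higher and 3 lower (adjusted p = 0.902), and epicardial genes 1 of 5 higher and 1 lower (adjusted p = 0.987), both the same adjusted over the list alone. Markers of endothelial, macrophage, erythroid and neural cells had 4, 3, 1 and 1 tested genes, too few for a test. Median, mean and test differed in sign for 6 lists, none of which passed: eIF3 subunits, fetal and hypertrophic genes, aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones, the COP9 signalosome and the interferon response.

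**Figure D3:**
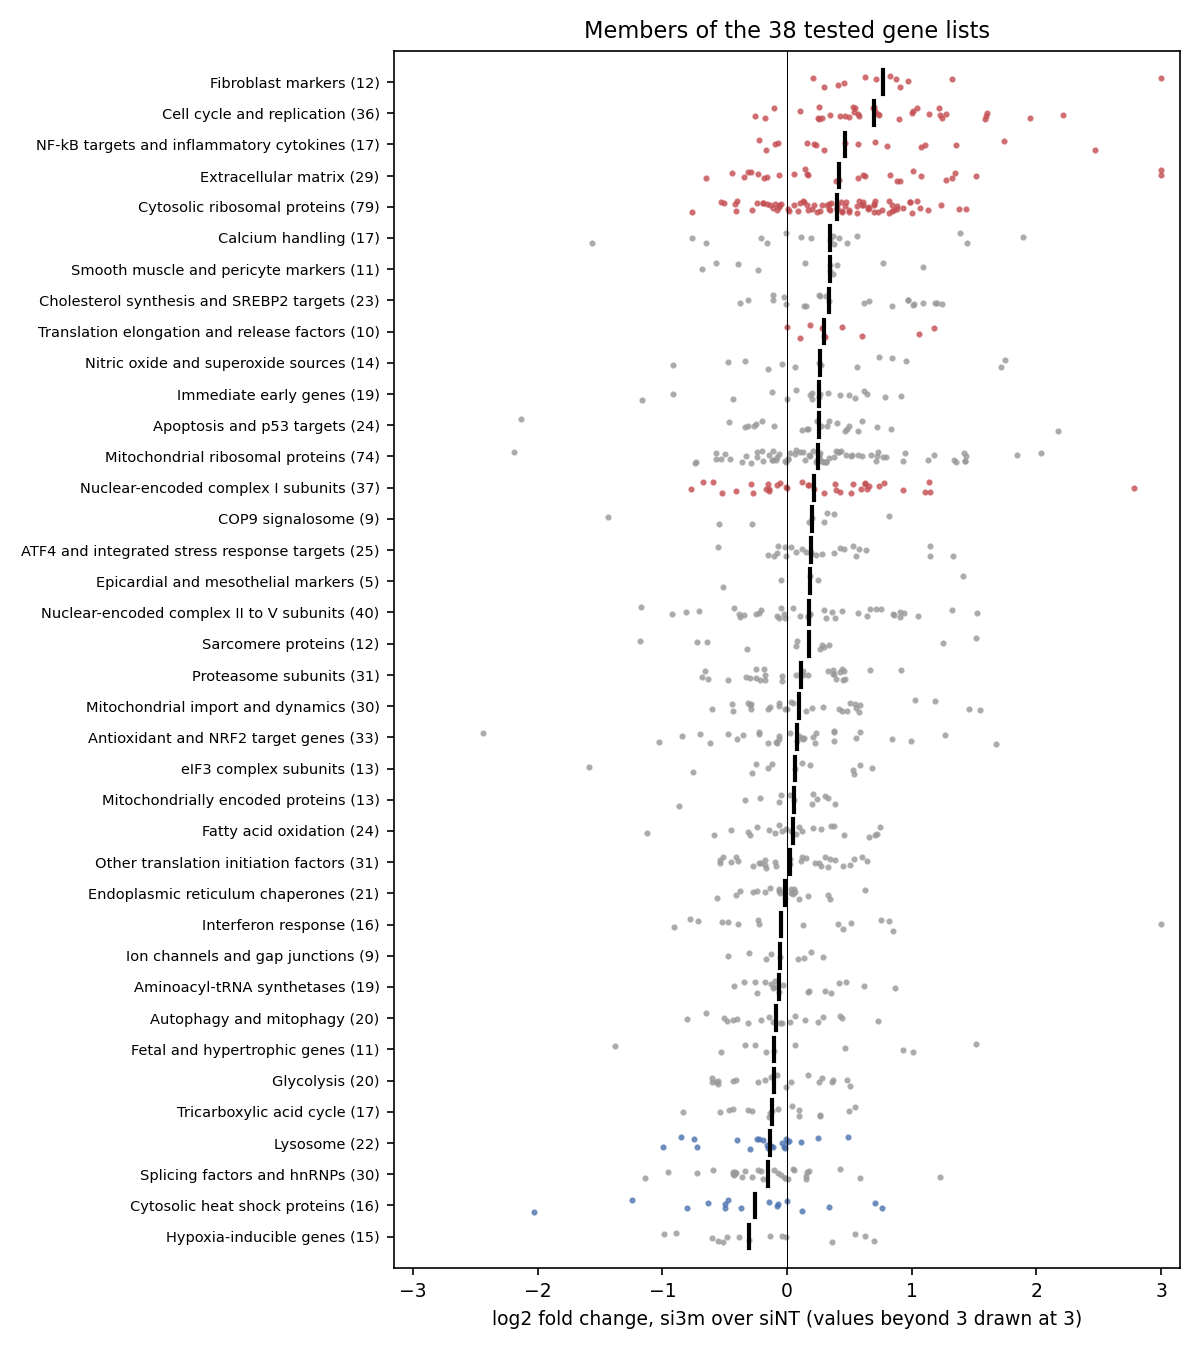
Log2 fold change of si3m over siNT for the members of 38 gene lists, a point per tested gene and a black line at each median, with the number tested in parentheses. Lists that passed camera with its preset correlation are red where higher and blue where lower, with medians from 0.77 for fibroblast markers to -0.26 for cytosolic heat shock proteins, and none passed with an estimated correlation.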

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

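The halved and thinned counts were chosen only after the even counts had been seen, unlike the other alternatives. Eif3m kept its direction in all 16 alternatives, with log2 values of -1.83 to -1.35 when a library was left out, but with robust quasi-likelihood its value of -1.59 had an adjusted p of 0.0522 (the cause was not tested). The count of 3528 changed genes became 2556 in DESeq2 and 3411 in limma-voom, 2537 to 3739 without 1 library, 3719 with halved counts and 3304 with thinned counts, at equal library totals. Requiring a log2 fold change over 1 left 899 genes, 583 higher and 316 lower, by construction. Replicate numbers did not pair the libraries (correlation of same-numbered deviations 0.01 over 7151 rows), and the replicate block gave 3694 genes, 3481 of them shared. The 9 lists became 15 with no filter, 18 in fry and 0 in camera with an estimated correlation, where 5 passed unadjusted. Fry tests a list without comparing it with other genes. Among the 9 lists, the estimated correlation exceeded the preset 0.01 only for complex I subunits (0.0135) and NF-kB targets (0.0316). It was 0.0036 for ribosomal proteins and -0.014 for the cell cycle. A stronger correlation between members therefore does not account for the other lost calls. With an estimated correlation, camera judges each list on the residual degrees of freedom, which are few with 2 libraries per group. With a preset correlation it does not. The camera p of ribosomal proteins went from 1.80e-09 to 0.0193, although their estimated correlation was below the preset one. Those losses follow from the small number of libraries and are weak evidence against the lists. Eif3l turned to -0.014 with total count scaling. The test of the antioxidant list, which passed in neither case, turned without siNT replicate 1 (median 0.039), with medians of 0.011 to 0.096 over the libraries left out (the cause was not tested for either). Over all tested genes and lists named and all alternatives, counts left out, 1452 values kept direction and side of the threshold, 51 no longer passed, 6 newly passed and 2 turned. Most of these genes were named for large changes or small p-values in the same libraries. The tally therefore does not measure how stable the 3528 calls are, of which 2555 were shared by DESeq2 and 3049 by thinned counts. It also includes the fits without 1 library, which leave 1 sample in a group. For Eif3m those fits gave far smaller adjusted p than the main fit, so they were no stricter test of it. Simulated 1.5-fold changes were recovered in 22.6% of 62 genes, with the same dispersion of 0.0109 for every gene. The fit of the data called smaller changes in genes with many counts, such as Ctsl at 1.18-fold. The simulated share is therefore no estimate of what was missed here.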

Other observations

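The tests of histone genes, microRNA genes and cardiomyocyte genes were made only after the results were seen. So were the choice of Vcan, Cd44, Tnfaip6, Matn3, the small nucleolar RNA rows, Rmrp and Rn5s, and the split at 10 CPM of genes around tRNA genes. Rules for the other tests of genes around tRNA and snoRNA genes were set before those tests were run. The rises of Mettl26 and Casp16 had already been seen and prompted them. Histone genes, most of which are translated while DNA is replicated, were higher in si3m: of 30 tested, 17 rose and 13 did not pass, with a median log2 of 0.98, unchanged with Hist1h2aa, at 0 in siNT, set to its bound. Camera gave p = 1.78e-09 for this class, and p = 0.0238 with an estimated correlation, neither adjusted for the choice of class. Near-identical histone copies share reads. Beside Has2, the hyaluronan-binding proteoglycan gene Vcan rose 2.03-fold (log2 1.02, SE 0.083, edgeR adjusted p = 2.01e-07) and the hyaluronan receptor gene Cd44 1.23-fold (log2 0.29, SE 0.055). Tnfaip6 had a log2 value of -0.02 and did not pass, and Has1 and Has3 had at most 4 and 14 counts in any library. Matn3, a matrix protein of cartilage, was the other of 2 genes with at most 10 counts in both siNT libraries and at least 100 in both si3m libraries, and rose 6.73-fold (log2 2.75, SE 0.34). Mir222, chosen after its values were seen, had 14 and 20 counts in siNT and 24 and 402 in si3m, so that 1 library sets its rise. LOC100911825 had 11673 and 300 counts in the siNT libraries.

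Most of 18 genes of cardiomyocytes were near the counting floor whichever siRNA was given, with 10 to 15 of them at 6 counts or fewer in a library. Myh6 had 2, 2, 6 and 10 counts, Tnni3 and Nppa had 0 in each, and the highest were Tnnc1 with 224, 268, 605 and 500, Ttn with 158, 172, 228 and 170 and Tnnt2 with 26, 26, 124 and 108 (siNT replicates 1 and 2, then si3m replicates 1 and 2). Too little depth is excluded, since the 18 markers summed to at most 131.7 CPM of the library total while Col1a1 stood above 3845. Loss of reads to paralogs is argued against but not excluded. Of 7 markers taken as having no close paralog (Ttn, Ryr2, Tnnt2, Nppa, Nppb, Actn2 and Mybpc3), 6 stayed under 20 CPM in every library. Ryr2, Tnnt2, Actn2 and Mybpc3 do belong to gene families. As a hypothesis, the cultures may have held few cardiomyocytes, because 7 mesenchymal genes (Col1a1, Col1a2, Col3a1, Postn, Vim, Acta2 and Tagln) summed to at least 84.05 times the 18 markers in each library, though such cells share some of these genes with other types. Fibroblast genes Tcf21 and Pdgfra had at most 0 and 18 counts. The myoblast genes Cdh15 and Myod1 had 68 to 182 and 8 to 54, but Myf5 and Pax7 had 0 in each library. Of cardiac transcription factor genes, Gata4 and Mef2c had 74 to 194 and 300 to 420, and Nkx2-5, Tbx5 and Hand2 at most 20, 8 and 6. Which cells were grown was not tested.

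MicroRNA genes were lower in si3m as a class, with 78 of 120 falling, 1 (Mir222) rising and a median log2 of -1.17 (camera p = 2.35e-52, and p = 0.0426 with an estimated correlation). A lower yield of every kind of non-coding RNA is excluded, since 314 other non-coding rows, 263 of them long non-coding RNA and 35 pseudogenes, had a median log2 of -0.1411 (95% bootstrap interval -0.24 to -0.05). The fold changes of the microRNA genes spread 3.462 times their median standard error, which argues against 1 loss factor as their only difference. That standard error holds only the spread between replicates that may be technical, and several microRNA rows overlap other genes. A common loss with other differences on top is therefore not excluded. A loss shared by microRNAs and small nucleolar RNAs stays open, since the 3 tested rows of small nucleolar or Cajal body RNAs, Scarna15, Scarna3 and Snora58, also fell (log2 -2.06, -1.30 and -1.38), whereas the structured RNAs Rmrp and Rn5s rose (log2 0.91 and 1.55). A preparation that differed between the groups, for example in the width of the fragment size selection, cannot be told apart from an effect of the siRNA, because group and preparation may coincide and replicates of a group were closer (median absolute log2 difference 0.2715) than the groups, although 25 of the 120 were over 2-fold apart between si3m replicates against 4 between siNT replicates. The size of the fragments was not analysed here.

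Mettl26 spans a tRNA gene in the GRCr8 annotation and Casp16 spans 4, which led to the hypothesis that tRNA fragments counted in the gene around them may raise such genes. The test did not bear this out as a set: 6 of 124 genes with a tRNA gene inside were over 2-fold higher (4.84%, against 4.45% of 10420 others, with an odds ratio of 1.09 and a 95% interval of 0.390 to 2.46), where matched sets gave a median of 3 (permutation p = 0.110). The 6 include Mettl26 and Casp16, which prompted the test. Fragments of any small structured RNA counted in the gene around it stay open: 6 of 297 genes with a snoRNA gene inside were over 2-fold higher (2.02%, against 4.53% of others; odds ratio 0.435, 95% interval 0.157 to 0.965) and matched sets gave a median of 10 (permutation p = 0.939), but the 3 tested small nucleolar or Cajal body RNA rows fell, so that such fragments need not raise the gene around them, and genes around other structured RNAs were not tested. Higher depth of the si3m libraries stays open for the 6 as a set, since 4 still passed after thinning (66.7%, under the 80% set beforehand). The 3 of at least 10 CPM, Mettl26, Casp16 and Ndufs4, all passed (log2 3.52, 2.63 and 1.16), so their calls did not need the extra depth. At their counts they could hardly fail, and random thinning leaves ratios between libraries unchanged on average. It therefore cannot judge depth as a cause of their fold changes. Of the others 1 (LOC102556096) passed. Fcgr2a (log2 1.29, SE 0.36) lost its call as its SE grew (log2 1.11, SE 0.45), and Slc52a2 (log2 1.88, SE 0.52) was removed by the low-count filter. Whether the reads of Mettl26 and Casp16 come from their tRNA genes was not tested, since read positions were not analysed here.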
